A study of Sus scrofa domesticus with 36 samples.

How the data were processed

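RNA was taken from longissimus dorsi muscle and from subcutaneous backfat (the latter between rib 8 and the last rib) of 18 pigs of 1 commercial cross, euthanised 3 weeks after weaning. Per the labels' protocols, RNA was isolated with a MagMAX total RNA kit, libraries were made with a TruSeq RNA kit, and both ends were read for 100 nt on a HiSeq 2000. The labels' protocols do not say that the libraries kept strand, so reads of overlapping or antisense genes could not be told apart. The labels also give an age of 16 to 17 days and name the stage weaning, which is at odds with 3 weeks after it, and the age at sampling is not given in the sources used here.

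The authors deposited 1 table of expected counts, not normalised, with 25322 Ensembl pig genes and 36 libraries. GSNAP and HTSeq are named per the submitters' processing notes, without versions, and the genome build and annotation are not given in the sources used here. The deposited expected counts run in steps of 0.5, with 35.1% of gene values not whole, for a reason not given in the sources used here. They were rounded to whole numbers (ties to the even number) for all tests. A further 5 lines name no gene and stayed out of library sizes and of the genes tested. Counts that fell in no annotated gene made up 34.5% ± 5.60 of an adipose library and 19.9% ± 4.01 of a muscle library (SD, n = 18), and counts shared by several genes made up 0.759% ± 0.0789 and 0.729% ± 0.0853. A symbol was found for 11804 of the 25322 gene IDs, and for 8495 of the 12542 genes tested, in a table of current names, so a symbol may postdate the annotation that was counted. No genome sequence was used here, so no coordinates, gene lengths or sequence checks are given, and a Sscrofa11.1 gene table served only for the order of 2 genes and the chromosomes of 1 list. Columns left unused in the table numbered 0.

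Tissue and pig number were taken from the sample titles. The labels state that growth classes were paired by litter size and parity of the sow, but give neither class nor pair of a pig, so neither entered a test. All pigs are separate animals, and the libraries with 1 number come from 1 animal, so the numbers pair the samples. As a check, the deviations of a pig's adipose library from the adipose mean correlated with those of its own muscle library at 0.171 on average (0.038 to 0.343), against -0.0101 on average with the muscle of other pigs, where the highest value was 0.676, above that of every own pair. The own muscle was the best match for 7 of 18 pigs over all genes, and for 12 of 18 over the genes called as correlated when that pig was left out. A check by sex-linked genes was not done, since those genes carry no symbol in the tables used here.

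The tissue comparison was made with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (robust fit, design of tissue alone, trimmed-mean factors, the tool's default filter on low counts), which kept 12542 genes. P values were adjusted by Benjamini-Hochberg, the threshold was an adjusted p of 0.05, and the SE is the log2 difference divided by the square root of the F statistic. Trimmed-mean factors averaged 1.62 in adipose and 0.626 in muscle. Gene lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01 for the 29 of 31 lists with at least 5 tested genes, and again with an estimated correlation. Correlations between tissues used log2 CPM (prior count 2) of the 11076 genes with at least 1 CPM in at least 15 of 18 libraries of each tissue. They were tested by Spearman's rho with 100000 two-sided permutations of the pig numbers, in Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and numba 0.67.0. List scores are the mean over list genes of values standardised over the 18 libraries of a tissue. The spread test swapped the centred list means of both tissues within pigs 100000 times. Figures were drawn with Matplotlib 3.10.9.

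The design, the named-gene rule, the 31 gene lists and most alternatives were fixed before the data were examined. The alternatives that doubled the values, left out sets of named pigs or removed the ACTA1 level in adipose were chosen afterwards. Named genes have a symbol and are the 12 in each direction with the largest log2 difference among those with an adjusted p under 0.05, at least 50 CPM in the higher tissue and 1 direction in all 18 pigs. To these come up to 4 genes of each list with the highest mean CPM, up to 12 genes with the highest correlation between tissues, and in each tissue the 6 genes with the largest SD of log2 CPM among those with a mean of at least 10 CPM. Of the genes so named, 2 are not reported here. The lists cover adipocyte identity, fatty acid synthesis, lipolysis, 5 groups of muscle genes, energy metabolism, matrix, progenitors, immune cells, interferon, antigen presentation, vessels, skin, nerve, blood, clock, cell cycle, protein breakdown, growth hormone, glucocorticoid, immediate early, heat shock and brown-like genes. A list of secretory epithelium genes and a list of sebaceous gland genes were added after the widest genes had been seen and before they were tested.

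Alternatives changed 1 choice at a time: the pig number as a block, relative-log factors, library totals alone, abundant genes left out, no filter, a stricter filter of 10 CPM, DESeq2 1.42.0, limma-voom, counts thinned to the smallest library, a test against 2-fold, each pig left out, 2 sets of named pigs left out, values doubled to whole numbers, the ACTA1 level in adipose removed, other correlations, scores and measures of spread, and removal of the first principal component or of the library total. The tests were tried on simulated data with known answers. For the tissue comparison, with 12428 genes and 50 changed genes per size, 54.0% of 1.5-fold, 98.0% of 2-fold, 100% of 3-fold and 100% of 4-fold changes were recovered, and 3.30% of calls were false. Both simulated tissues shared 1 profile apart from these 200 changed genes, whereas most genes differ between the real tissues. The 3.30% thus does not cover errors that the scaling can bring when most genes differ. Camera called the 1 simulated list that was changed and 0% of 100 unchanged lists, which does not measure how many changed lists it would miss. The simulated genes varied independently of each other. The 0% thus does not cover lists whose genes vary together, such as the sarcomere list (estimated correlation 0.898). For the correlation between tissues, over 2000 simulated genes, 99.0% of true relations with a correlation of 0.9 and 0.316% of absent relations passed. Weaker true relations were not simulated, so the share of them that would be missed is not known. For the spread comparison, the test of 200 simulated lists gave an unadjusted p under 0.05 for 8.00% of lists with equal spread and for 96.0% of lists with a 3-fold ratio, so its p values run somewhat low. Library totals of 2990913 to 6216459 gene counts set the depth, and SEs and permutation p values carry the spread between pigs.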

Results

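Gene expression was measured by RNA sequencing in the longissimus dorsi, the long muscle of the back, and in the subcutaneous backfat of 18 young commercial crossbred pigs sampled 3 weeks after weaning. Each pig gave 1 muscle library and 1 adipose library, and the 36 libraries are named here by tissue and by the pig's name in the labels (Sample_656 and so on). The submitters drew 9 pigs from the slowest growers (up to percentile 10 of growth rate) and 9 from percentiles 60 to 70, out of 1054 pigs. The labels used here do not give the class of a pig, so growth classes were not compared here. The comparisons below are between the 2 tissues, and over pigs within and between tissues. The values are counts per gene for 25322 genes. Adipose libraries held between 2990913 (pig Sample_656) and 5373406 (pig Sample_572) gene counts, with a mean of 4545110 ± 564603 (SD, n = 18). Muscle libraries held between 4716541 (pig Sample_735) and 6216459 (pig Sample_998), with a mean of 5263400 ± 351374 (SD, n = 18). Counts were spread over more genes in adipose, where the 10 most abundant genes of a library took 10.6% ± 1.87 of the counts (SD, n = 18), than in muscle, where they took 29.2% ± 6.0 (SD, n = 18). All levels are counts-per-million (CPM) after scaling with trimmed-mean factors, and every log2 difference is adipose minus muscle with its standard error (SE), over 18 libraries of each tissue. The files carry no genome build, so genes are given by symbol without coordinates.

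The first comparison asked which genes differ between backfat and back muscle. PCK1, the enzyme that feeds glycerol backbone synthesis in fat cells, was at 302 ± 141 CPM in adipose and 2.65 ± 2.88 CPM in muscle (SD, n = 18), a log2 difference of 6.81 (SE 0.298). PLIN1, the coat protein of the fat cell's lipid droplet, differed by 6.39 (SE 0.306), and CIDEC, which fuses lipid droplets, by 5.22 (SE 0.340). The kinase gene SGK2 had the farthest difference on this side, 7.04 (SE 0.271), among genes with a symbol, at least 50 CPM in adipose and the same direction in all 18 pigs, while GLYATL2 and CPHL1, which are described with the widest genes, lay farther but not in the same direction in every pig. Outside lipid handling, the tight junction gene CLDN4 differed by 6.38 (SE 0.378), the matrix genes CILP2 and POSTN by 6.13 (SE 0.545) and 5.04 (SE 0.318), and the protease gene ADAMTS4 by 4.91 (SE 0.352). The other top genes on this side were PPP1R1B (5.70), ITIH3 (5.09), MEIOB (4.76) and PTPRU (4.73). On the muscle side, MYBPC2, a fast myosin-binding protein, was at 14469 ± 3974 CPM in muscle against 113.9 ± 173 CPM in adipose (log2 difference -6.99, SE 0.561). ATP2A1, the calcium pump of fast fibres, differed by -6.90 (SE 0.551), PYGM, the muscle glycogen phosphorylase, by -6.78 (SE 0.585), and the M-band protein MYOM2 by -6.81 (SE 0.563). MYH13 lay farthest by the same criteria, at -7.49 (SE 0.608), but it belongs to a cluster of closely similar myosin genes whose reads the counting could split, so its level is uncertain. The remaining top genes on this side were MYBPH (-7.08), SYPL2 (-6.86), SMYD1 (-6.83), SRL (-6.82), SYNPO2L (-6.82), CA14 (-6.80) and KLHL31 (-6.75). All 24 of these genes differed in the same direction in 18 of 18 pigs, with adjusted p between 3.8e-24 (PPP1R1B) and 5.49e-13 (CILP2) by edgeR's quasi-likelihood test. A further 2 genes on the adipose side and 11 on the muscle side met these criteria and lay as far out but carry no symbol.

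Of 12542 genes tested, 5853 were higher in adipose and 4919 were higher in muscle at a Benjamini-Hochberg adjusted p under 0.05, and 3591 and 3165 of these pointed the same way in all 18 pigs. Differences of at least 2-fold made up 56.1% of the calls, with 3424 genes higher in adipose and 2620 higher in muscle. The split depended on the scaling. With library totals alone, in place of trimmed-mean factors, the median gene moved from 0.14 to 1.5 on the log2 scale, and 10148 genes were called higher in adipose and 1520 higher in muscle (87.0% against 54.3% of calls on the adipose side), and the medians of the protein breakdown, clock, growth hormone, heat shock, brown-like and glucocorticoid lists turned from the muscle to the adipose side. All differences given here are relative to the trimmed-mean scaling.

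**Figure D1:**
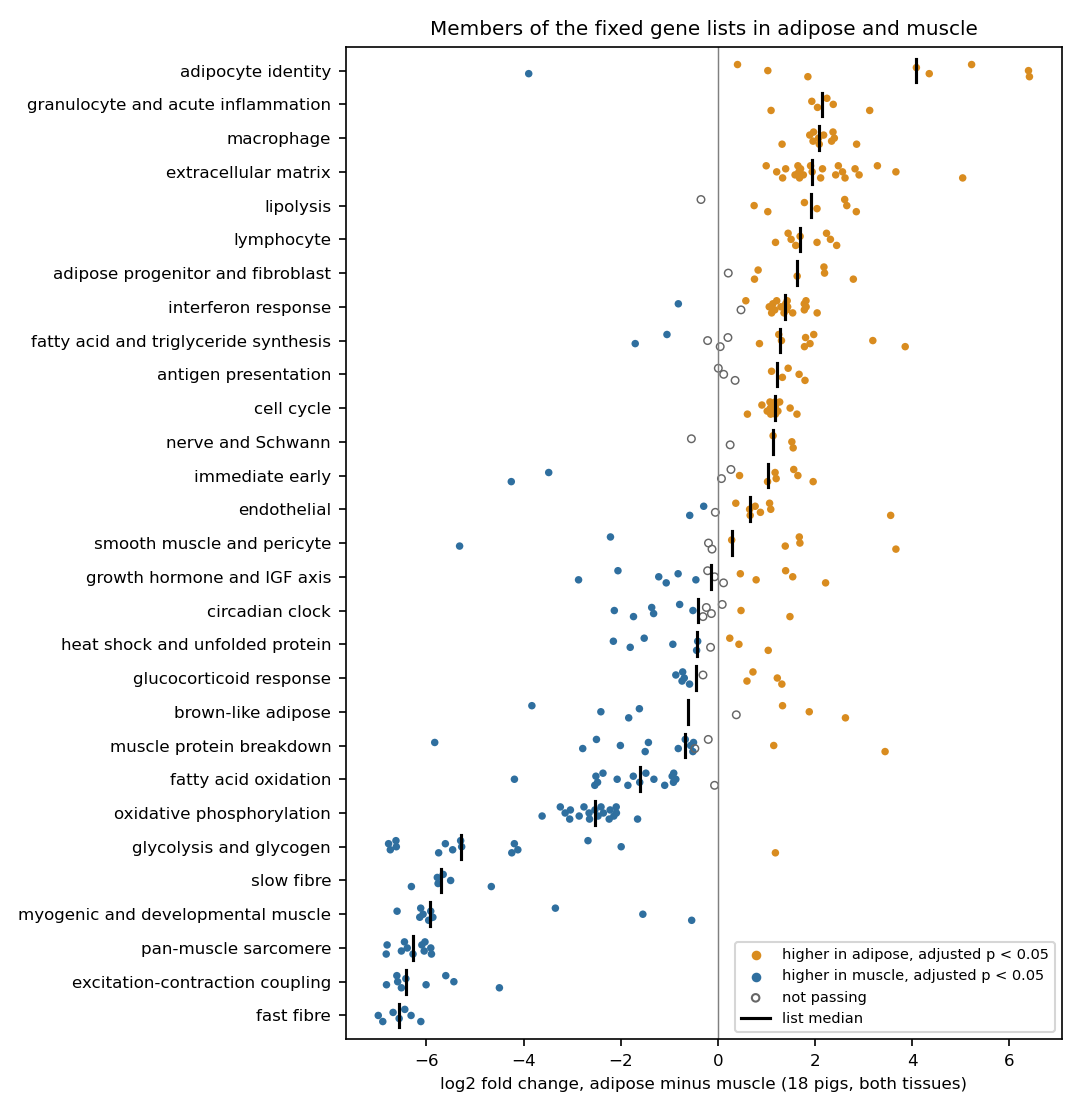
Each point is 1 gene of a fixed list, placed on the horizontal axis by its log2 difference, adipose minus muscle, over 18 pigs. Orange and blue points passed the test on the adipose and muscle side, open points did not, and black bars mark list medians, which run from -6.56 for fast fibre genes to 4.08 for adipocyte identity genes.

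Lipid and connective tissue lists stood on the adipose side. Of 9 adipocyte identity genes tested, 8 were higher in adipose, among them PLIN1, PLIN4 (0.40, SE 0.159) and CFD (1.85, SE 0.143), which encodes adipsin. The exception was GPD1, a glycerol phosphate dehydrogenase, at -3.89 (SE 0.188). Camera called this list (adjusted p = 0.00966; adjusted p = 0.359 with an estimated correlation). Of 8 lipolysis genes, 7 were higher in adipose, including hormone-sensitive lipase LIPE (2.61, SE 0.311) and PNPLA2, the triglyceride lipase (0.75, SE 0.162), and 1 did not pass (camera adjusted p = 0.0252; adjusted p = 0.360 with an estimated correlation). Of 14 genes of fatty acid and triglyceride synthesis, 9 were higher in adipose, 2 were higher in muscle and 3 did not pass, and the list was not called (camera adjusted p = 0.106). Fatty acid synthase FASN was at 1.97 (SE 0.213) and the desaturase SCD at 1.78 (SE 0.383), while ACSS2, which activates acetate, was at -1.70 (SE 0.137). All 23 extracellular matrix genes were higher in adipose. The fibrillar collagen COL3A1 was at 11845 ± 4769 CPM in adipose and 3088 ± 1379 CPM in muscle (SD, n = 18; log2 difference 1.94, SE 0.225), COL1A2 was at 2.91 (SE 0.323), and the proteoglycan DCN was at 2.62 (SE 0.192). The matrix list had a camera adjusted p = 2.42e-06, with an adjusted p = 0.388 with an estimated correlation. Of 7 progenitor and fibroblast genes, 6 were higher in adipose, including CLEC3B (2.79, SE 0.129) and PDGFRA (2.19, SE 0.156; camera adjusted p = 0.0179; adjusted p = 0.360 with an estimated correlation). Under library totals alone these lists stayed on the adipose side. That scaling moves genes toward adipose, so it could not have turned them.

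Contractile and energy lists stood on the muscle side. All 11 sarcomere genes were higher in muscle, led in level by ACTA1, the skeletal muscle actin, at 148438 ± 74678 CPM in muscle and 2275 ± 4319 CPM in adipose (SD, n = 18; log2 difference -6.03, SE 0.725). A few pigs carried the adipose mean, and the adipose median was 644 CPM. The same was true of all 7 fast fibre genes, such as MYL1 (-6.44, SE 0.676) and TNNC2 (-6.68, SE 0.608), and of all 6 slow fibre genes, such as TNNC1 (-5.65, SE 0.562) and TNNI1 (-5.77, SE 0.583). Camera gave these 3 lists adjusted p = 4.42e-05, 0.00346 and 0.00529, and adjusted p = 0.425, 0.425 and 0.462 with an estimated correlation. All 9 genes of excitation-contraction coupling were higher in muscle, including the calcium channel CACNA1S (-6.51, SE 0.560; camera adjusted p = 8.6e-06; adjusted p = 0.359 with an estimated correlation). All 10 myogenic and developmental genes were higher in muscle, including MEF2C (-3.34, SE 0.155) and the developmental myosins MYH8 and MYH3, whose reads similar myosins may share (camera adjusted p = 0.000376; adjusted p = 0.359 with an estimated correlation; 8 higher in muscle and 1 higher in adipose under library totals alone). Glycolysis and glycogen genes were higher in muscle in 14 of 15 cases, and GAPDH, often used as a reference gene, differed by -5.61 (SE 0.363), ENO3 by -6.62 (SE 0.590) and LDHA by -5.75 (SE 0.338; list camera adjusted p = 6.22e-06; adjusted p = 0.359 with an estimated correlation). The muscle side of these lists varied with the adipose libraries: ACTA1 in adipose ran from 52.4 CPM (pig Sample_991) to 17526 CPM (pig Sample_731), and 32 sarcomere, fibre and coupling genes had a median Spearman rho of 0.960 with it over those libraries.

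All 19 genes of oxidative phosphorylation were higher in muscle, by less than the contractile genes. The list median was -2.53, and examples were SDHA at -2.47 (SE 0.0856) and UQCRFS1 at -3.14 (SE 0.105; camera adjusted p = 1.17e-10; adjusted p = 0.359 with an estimated correlation). Of 17 genes of fatty acid oxidation, 16 were higher in muscle and 1 did not pass, and under library totals alone 9 were higher in muscle and 5 higher in adipose. The 2 subunits of the trifunctional protein, HADHA and HADHB, were at -1.48 (SE 0.105) and -1.61 (SE 0.0828), and the list had a camera adjusted p = 7.86e-06 (adjusted p = 0.359 with an estimated correlation). Of 15 genes of muscle protein breakdown, 11 were higher in muscle and 2 higher in adipose, whereas under library totals alone 4 were higher in muscle and 9 in adipose (camera adjusted p = 0.0382; adjusted p = 0.549 with an estimated correlation). EIF4EBP1, a brake on translation, was at -2.50 (SE 0.172), and ubiquitin UBB was at -0.51 (SE 0.0835) but at 0.84 under library totals alone.

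Immune genes were mostly higher in adipose. All 11 macrophage genes were higher in adipose, including the mannose receptor MRC1 (2.85, SE 0.244), the complement gene C1QA (1.96, SE 0.224) and CD14 (2.40, SE 0.252; camera adjusted p = 0.00371; adjusted p = 0.502 with an estimated correlation). Of 20 interferon response genes, 18 were higher in adipose, with OAS2 at 2.04 (SE 0.245) and MX1 at 1.81 (SE 0.244), 1 was higher in muscle and 1 did not pass, while under library totals alone all 20 were higher in adipose. The list had a camera adjusted p = 0.00446 (adjusted p = 0.597 with an estimated correlation). All 9 lymphocyte genes, all 6 granulocyte and acute inflammation genes and all 16 cell cycle genes were higher in adipose, such as CD2 (2.04, SE 0.280), the chemokine CCL2 (2.24, SE 0.346) and TOP2A (1.12, SE 0.338), but their camera adjusted p values were 0.0756, 0.0927 and 0.0876. With the pig number as a block these 3 lists passed at the preset correlation, at adjusted p = 0.0157, 0.0359 and 0.00587, while with an estimated correlation and no block their adjusted p values were 0.597, 0.540 and 0.649. Antigen presentation had 5 of 8 genes higher in adipose, including SLA-DQB1 (1.33, SE 0.179), and 3 not passing (camera adjusted p = 0.133, and 0.0412 with the pig number as a block; adjusted p = 0.597 with an estimated correlation and no block). SLA genes vary between animals and resemble each other, so their counts are uncertain. Lymphocyte genes also passed without pigs Sample_731, Sample_391, Sample_176 and Sample_911 (camera adjusted p = 0.0479). In all, camera called 15 of 29 lists tested, 6 on the adipose side and 9 on the muscle side, and 0 of these calls held with an estimated correlation. The counts adjusted over the list alone equalled those over all genes except for the interferon list, where 19 genes were higher in adipose.

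Markers of other cells that the samples could hold were mixed. Of 11 endothelial genes, 8 were higher in adipose, with the lymphatic receptor LYVE1 at 3.55 (SE 0.295) and PECAM1 at 0.77 (SE 0.111), 2 were higher in muscle and 1 did not pass (camera adjusted p = 0.135). Smooth muscle and pericyte genes were split into 5 higher in adipose, 2 higher in muscle and 2 not passing (camera adjusted p = 0.606), with TAGLN at 1.39 (SE 0.153) and SYNPO2, which skeletal muscle also expresses, at -5.32 (SE 0.243). Of 5 nerve and Schwann cell genes, 3 were higher in adipose and 2 did not pass (camera adjusted p = 0.357), with CNP at 1.14 (SE 0.109). Only 3 keratinocyte and 2 erythroid genes were measured well enough to test, too few for camera. TP63 was higher in muscle at -3.85 (SE 0.360), while DSP at -0.59 (SE 0.297, adjusted p = 0.0631; -1.09, adjusted p = 0.00364 with the pig number as a block) and KRT10 at -0.01 (SE 0.111, adjusted p = 0.928) did not pass, and both were positive under library totals alone (0.83 and 1.37). SLC4A1 was higher in adipose at 0.89 (SE 0.148), and HBB, the beta chain of haemoglobin, was at -0.73 (SE 0.438, adjusted p = 0.119; -0.68, adjusted p = 0.000164 with the pig number as a block; 0.74 under library totals alone).

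**Figure D2:**
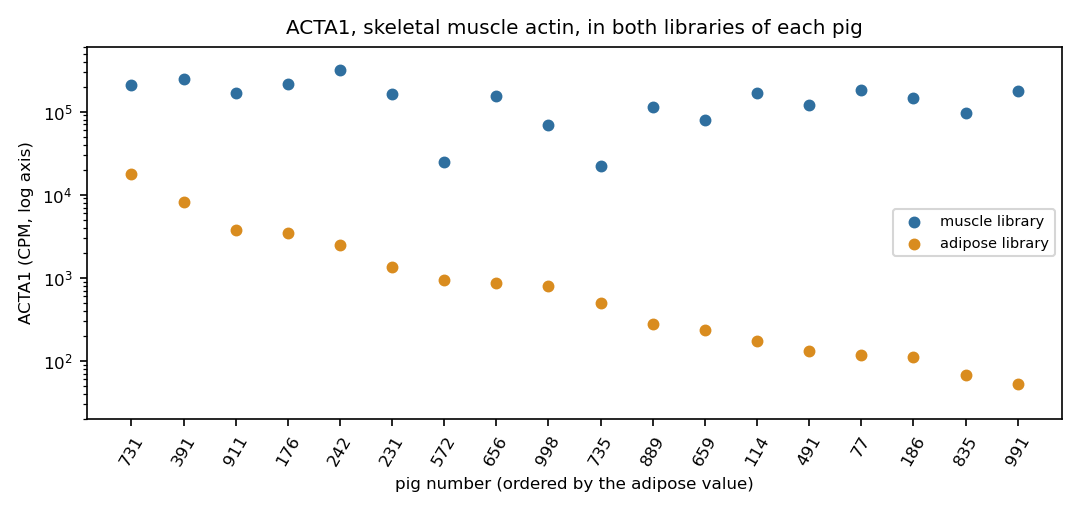
ACTA1 level (CPM, log axis) in the adipose library (orange) and the muscle library (blue) of each of the 18 pigs, ordered by the adipose value. Adipose values run from 52.4 to 17526 CPM, and muscle values are lowest in pigs Sample_735 (22408 CPM) and Sample_572 (25059 CPM).

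The second comparison asked which genes vary together in the 2 tissues of a pig. HBB led, with a Spearman rho of 0.905 over 18 pigs (permutation p = 1e-05, the smallest the permutations can give; adjusted p = 0.0123) and a Pearson r of 0.895 (adjusted p = 0.00554), or 0.868 without the 2 pigs farthest from the median; its counts may include reads of related globins. OAS2, an interferon-induced antiviral gene, had a rho of 0.853 (adjusted p = 0.0148) and an r of 0.835 (0.897 without 2 pigs). TOP2A, the topoisomerase of dividing cells, had a rho of 0.843 (adjusted p = 0.0148) and an r of 0.808 (0.782 without 2 pigs), and FANCD2, a DNA repair gene, a rho of 0.862 (adjusted p = 0.0123) and an r of 0.868 (0.884 without 2 pigs). The other leading genes were MPDU1 (rho 0.884), CBLB (0.864), ZNF34 (0.858), BCKDK (0.847), RHNO1 (0.847), ITPKC (0.843), DNAJC7 (0.831) and TCTN2 (0.820), with adjusted p of at most 0.0269 for DNAJC7 and an r of at least 0.638 without 2 pigs for TCTN2. Of these 12 genes, 9 lost the call with the first principal component of each tissue removed, 8 without pigs Sample_656, Sample_572 and Sample_735, 3 with the ACTA1 level in adipose removed and 3 with the library total removed. Of 11076 genes tested, 61 passed in a two-sided permutation test with 100000 permutations and Benjamini-Hochberg adjustment, 35 of them with a symbol, and 61 had a positive rho. The median rho was 0.185 (permutation p = 1e-05, the smallest the permutations can give), with 75.1% of genes above 0. By Pearson 205 genes passed. The count was lower with the first principal component of each tissue removed (12 genes), with the ACTA1 level in adipose removed (20 genes) or without pigs Sample_656, Sample_572 and Sample_735 (18 genes). It also moved by over 1.5 times when pig Sample_391 (38 genes), Sample_491 (27), Sample_656 (38), Sample_889 (36) or Sample_911 (36) alone was left out.

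Among the fixed lists, antigen presentation held the most genes that passed over all genes, and the interferon list the most that passed adjusted over the list alone. Of its 8 genes, 4 passed over all genes and 7 passed adjusted over the list alone, and the 4 were the class II genes SLA-DQB1 (rho 0.806) and SLA-DMA (0.792) and both genes of the peptide transporter, TAP1 (0.794) and TAP2 (0.781). TAP1 and TAP2 were named after their values were seen. In the interferon list 2 of 19 genes passed over all genes, MX1 and OAS2, and 16 passed adjusted over the list alone. In the cell cycle list 2 of 13 passed over all genes, TOP2A and TPX2, and 9 passed adjusted over the list alone. In the macrophage list 0 of 11 passed over all genes and 8 passed adjusted over the list alone, and in the lymphocyte list these counts were 0 and 2 of 5. The glucocorticoid list had 2 of 10 on both counts, PDK4, which inhibits pyruvate dehydrogenase (rho 0.787), and PER1, a clock gene (rho 0.775). Fatty acid synthesis and fatty acid oxidation each had 5 genes that passed adjusted over the list alone, of 13 and 17.

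List scores, the mean standardised level of a list's genes in a library, were then compared between the tissues of a pig for 29 lists, of which 6 passed. Antigen presentation had a rho of 0.771 (permutation p = 0.00027, adjusted p = 0.00783) and an r of 0.780 (permutation p = 0.00014), or 0.739 without the 2 farthest pigs. The glucocorticoid response list had a rho of 0.742 (permutation p = 0.00075, adjusted p = 0.0109) and an r of 0.592 (p = 0.00988; 0.484 without 2 pigs). Cell cycle genes had a rho of 0.684 (permutation p = 0.00209, adjusted p = 0.0202) and an r of 0.767 (p = 0.00027; 0.622 without 2 pigs). Macrophage genes had a rho of 0.649 (permutation p = 0.00467, adjusted p = 0.0288) and an r of 0.669 (p = 0.00258; 0.492 without 2 pigs), and interferon response genes a rho of 0.639 (permutation p = 0.00497, adjusted p = 0.0288) and an r of 0.654 (p = 0.00225; 0.761 without 2 pigs). Lymphocyte genes had a rho of 0.60 (permutation p = 0.01, adjusted p = 0.0484) and an r of 0.658 (p = 0.00285; 0.540 without 2 pigs). In adipose, 4 pigs lay below a gap of 25.3% of the range of interferon scores, and over the other 14 the rho was 0.437 (permutation p = 0.12), while for the cell cycle 15 pigs lay on one side of a gap of 24.6% and gave a rho of 0.464 (permutation p = 0.0832). Leaving out pigs by their score narrows its range and lowers rho by itself, so these values do not show that the relations rested on those pigs. Some calls ended in tests chosen after these results. With library total, share of counts outside genes and muscle RNA removed, the macrophage rho fell to 0.125 (permutation p = 0.621) and the lymphocyte rho to 0.426 (p = 0.0795). With the HBB level removed the glucocorticoid rho fell to 0.470 (p = 0.0512). With the first principal component of each tissue removed 0 lists passed, and the smallest adjusted p was 0.0771, for antigen presentation and cell cycle. Without pigs Sample_731, Sample_391, Sample_176 and Sample_911 the macrophage (rho 0.582, adjusted p = 0.152), lymphocyte (rho 0.429, adjusted p = 0.411) and interferon (rho 0.481, adjusted p = 0.302) lists no longer passed with fewer pigs, while oxidative phosphorylation (rho 0.701 against 0.276 over all pigs) and protein breakdown (0.692 against 0.309) then did (both adjusted p = 0.0452). Without pigs Sample_656, Sample_572 and Sample_735, 4 lists passed, and the macrophage (rho 0.536, adjusted p = 0.153) and lymphocyte (rho 0.579, adjusted p = 0.123) lists did not. With the median over genes as the score 5 lists passed, and the glucocorticoid list did not (adjusted p = 0.137).

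**Figure D3:**
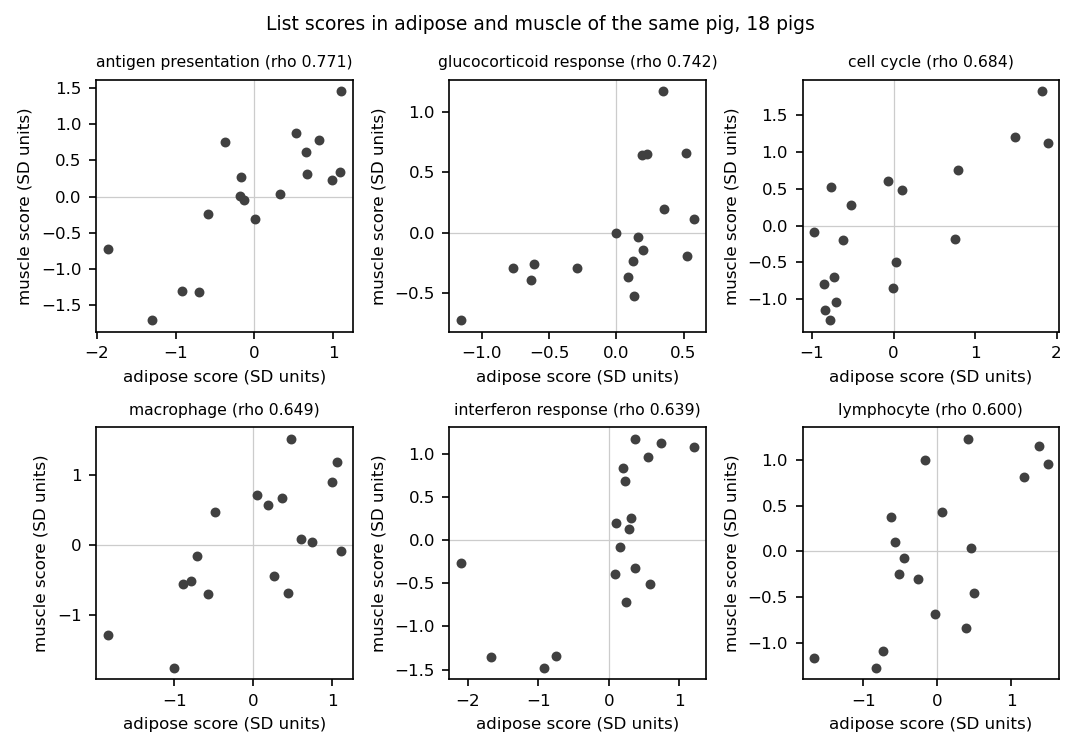
List scores in adipose (horizontal axis) and muscle (vertical axis) of the same pig, in units of the gene-wise SD, for the 6 lists that passed. Each point is 1 of 18 pigs, and rho runs from 0.60 for lymphocyte genes to 0.771 for antigen presentation genes.

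The third comparison asked in which tissue the pigs differ more. Contractile genes differed more between pigs in adipose than in muscle. The SD over pigs of the list mean was 1.83 in adipose and 0.385 in muscle for the sarcomere (permutation p = 6e-04, adjusted p = 0.0087), and 1.11 and 0.274 for excitation-contraction coupling (adjusted p = 0.0087). It was 2.16 and 0.659 for slow fibre genes (adjusted p = 0.0101) and 1.76 and 0.592 for fast fibre genes (adjusted p = 0.0125). Lipolysis genes had an SD of 0.372 in adipose and 0.182 in muscle (adjusted p = 0.0216), and myogenic genes 1.0 and 0.441 (adjusted p = 0.0463). Interferon genes had the larger SD in muscle, 0.734 against 0.478, but did not pass (adjusted p = 0.138). Of 29 lists, 6 passed the two-sided permutation test on log2 CPM. With the median absolute deviation in place of the SD, 2 lists passed, the sarcomere (adjusted p = 0.0281) and, with the larger spread in muscle, the interferon list (adjusted p = 0.0434). Without pigs Sample_731, Sample_391, Sample_176 and Sample_911, whose adipose held the most ACTA1, the log2 ratio of the SDs fell from 2.25 to 1.59 for the sarcomere, 2.02 to 1.18 for coupling, 1.71 to 1.04 for slow fibre and 1.57 to 1.04 for fast fibre genes, which still passed (adjusted p of at most 0.042). Without pigs Sample_656, Sample_572 and Sample_735, 7 lists passed, with glycolysis as the further one (adjusted p = 0.0185 against 0.508). The myogenic list did not pass with relative-log factors (adjusted p = 0.0552) or without pigs Sample_731, Sample_391, Sample_176 and Sample_911 (adjusted p = 0.279). With genes of 10 CPM or more, neither the lipolysis list (5 genes, adjusted p = 0.133, log2 ratio of the SDs 0.64 against 1.04) nor the myogenic list (adjusted p = 0.277) passed, and the coupling list was not tested.

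The biological coefficient of variation between pigs, fitted as 1 value common to all tested genes, was 0.299 in adipose and 0.269 in muscle, but the median of the values fitted per gene was 0.210 in adipose and 0.213 in muscle. The order of the tissues thus depended on the measure. The genes with the widest spread in adipose were CPHL1, from 1.05 CPM (pig Sample_176) to 1120 CPM (pig Sample_491), then CHIA (1.18 to 919 CPM), PHEROC (0.918 to 593 CPM), GLYATL2 (0.992 to 354 CPM), SCGB1D1 (0.524 to 281 CPM) and ACTA1. In muscle they were SMDT1, a subunit of the mitochondrial calcium uniporter (0 to 44.5 CPM), SNCG, the gamma-synuclein gene (0.721 to 96.1 CPM), GPX2, a glutathione peroxidase (1.67 to 198 CPM), PVALB, the calcium buffer parvalbumin (1.45 to 170 CPM), FBXO32 (2.99 to 440 CPM) and PNCK (0.241 to 71.3 CPM). FBXO32, the ubiquitin ligase known as atrogin-1, had a median of 9.89 CPM over the muscle libraries and stood at 440 CPM in pig Sample_572 and 294 CPM in pig Sample_735, the 2 pigs with the lowest ACTA1 in muscle. GPX2 was highest and PVALB and PNCK were lowest in the muscle of pig Sample_572.

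**Figure D4:**
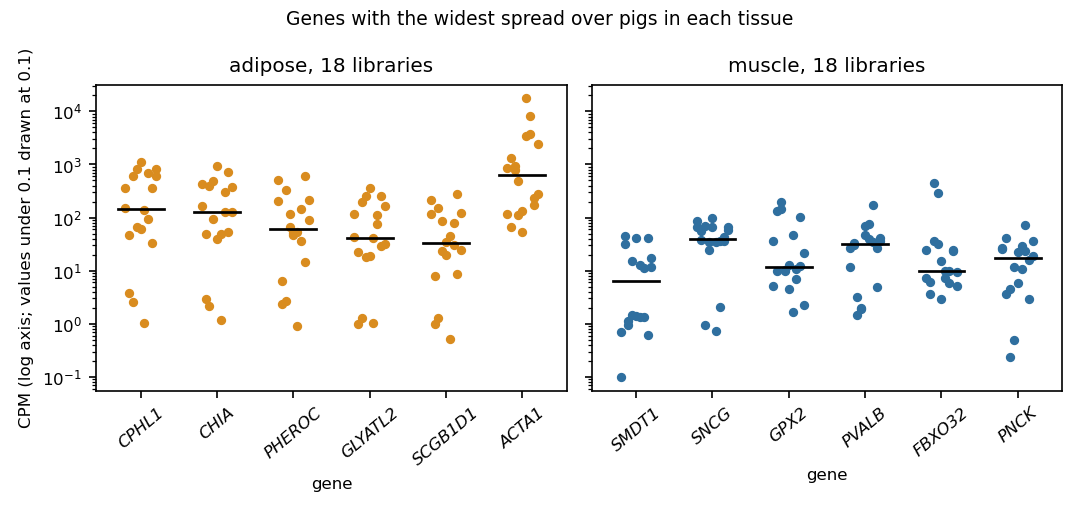
CPM (log axis) of the 6 genes with the widest spread over pigs in adipose (left) and in muscle (right), 1 point per library and a bar at the median of 18 libraries. CPHL1 spans 1.05 to 1120 CPM in adipose, and FBXO32 spans 2.99 to 440 CPM in muscle.

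The last comparison asked whether pigs high in 1 process are high or low in another, for 12 pairs of lists within a tissue fixed beforehand. In muscle, fast fibre and glycolysis scores rose together over pigs, with a rho of 0.781 (permutation p = 0.00024, adjusted p = 0.00288) and an r of 0.853 (permutation p = 2e-05; 0.790 without the 2 farthest pigs). Protein breakdown and glucocorticoid response scores also rose together in muscle, with a rho of 0.754 (permutation p = 0.00048, adjusted p = 0.00288) and an r of 0.775 (permutation p = 0.00025; 0.657 without 2 pigs). In adipose, adipocyte identity and fatty acid synthesis scores had a rho of 0.604 (permutation p = 0.00925, adjusted p = 0.037) and an r of 0.581 (permutation p = 0.0115; 0.535 without 2 pigs). Fast and slow fibre scores in muscle had a rho of -0.0155 (permutation p = 0.954), and fatty acid synthesis had a rho of 0.317 with lipolysis and -0.209 with macrophage genes in adipose (permutation p = 0.199 and 0.402). Slow fibre with oxidative phosphorylation (rho 0.490) and extracellular matrix with cell cycle (rho 0.498) in muscle did not pass by rank (both adjusted p = 0.0986) but did by Pearson (both adjusted p = 0.0277), and the first r fell from 0.595 to 0.270 without 2 pigs. The adipose pair no longer passed without the 2 farthest pigs (rho 0.521, adjusted p = 0.169), without pigs Sample_656, Sample_572 and Sample_735 (rho 0.568, adjusted p = 0.119) or without pigs Sample_731, Sample_391, Sample_176 and Sample_911 (rho 0.626, adjusted p = 0.076). Fewer pigs entered in each case. The breakdown pair no longer passed without pigs Sample_656, Sample_572 and Sample_735 (rho 0.621, adjusted p = 0.0937).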

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

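No test was run on the values in this part, which were looked up after the libraries had been summarised. They come from counts that fell in no annotated gene or in several genes, and there are no control samples to set them against. No comparison used these counts as expression. The share outside genes was only a library measure removed before list scores were compared again. The adipose library of pig Sample_656 had 53.8% of its counts outside annotated genes, the highest of 18, and also the fewest gene counts (2990913) and the fewest genes detected (17560). The muscle library of pig Sample_572 had 34.1% of its counts outside annotated genes, the highest of 18 muscle libraries, and it is also the library with the highest FBXO32 (440 CPM). Counts shared by several genes were highest in the adipose library of pig Sample_889, at 0.871%, and in the muscle library of pig Sample_491, at 0.938%. With 18 libraries per tissue, no single library was tested as standing apart from its group.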

How the results depend on the processing

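The settings that doubled the values, left out several named pigs or removed the ACTA1 level in adipose were chosen after the data had been seen. Under 13 alternatives, between 3955 and 10148 genes were higher in adipose apart from a test against 2-fold (2746), and the counts left the range of 1.5 times the reported one only with library totals alone (10148 higher in adipose, 1520 in muscle), with no filter (9077 in adipose, of 20197 genes tested) and with the test against 2-fold (2746 and 2282, a stricter question). The pig number as a block gave 5944 and 4944 genes, with 10706 of the 10772 calls kept in the same direction, and 19 lists. Among named genes and lists only DSP, HBB and the 4 further lists changed call, and these then passed. Leaving out each pig gave 5803 to 5947 genes higher in adipose and 4810 to 4940 higher in muscle.

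Camera called 0 lists with an estimated correlation, and fry, which tests whether a list's genes move on balance one way and compares no list with other genes, called 28. The count of genes correlated between tissues was 10 at 10 CPM or more (5871 genes tested), 205 by Pearson, 12 without the first component, 20 without the ACTA1 level in adipose and 18 without pigs Sample_656, Sample_572 and Sample_735, and leaving out each pig gave 27 to 88. The median rho stayed between 0.146 and 0.199, or 0.175 to 0.201 with each pig left out. Without the first component 0 list scores were correlated between tissues. By the median absolute deviation 2 lists differed in spread, and with genes of 10 CPM or more 3 of the 21 lists left did. Of the 12 list pairs 5 passed by Pearson and 1 without pigs Sample_656, Sample_572 and Sample_735. Except where fewer genes, lists or pigs entered, the cause was not tested.

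Of 1729 pairs of a named gene and a setting, 1658 kept direction and call, 40 lost the call, 6 gained it and 25 changed sign. With library totals alone the signs changed for PDK4 (0.38), ACSL1 (1.32), ACTA2 (1.27), DSP (0.83), KRT10 (1.37), HBB (0.74), PER1 (1.05), NR1D2 (5.01e-05), UBB (0.84), SQSTM1 (0.75), FOXO1 (0.74), AKT2 (1.29), STAT5A (0.94), KLF9 (0.59), FKBP5 (0.54), HSP90AA1 (0.96) and HSPD1 (0.45), which is what the shift of the median gene to 1.5 brings. The other changes were near 0: ACSL1 (0.051) and AKT2 (0.051) with the stricter filter, ACTA2 (0.031) and KRT10 (0.0076) without pigs Sample_731, Sample_391, Sample_176 and Sample_911, KRT10 with abundant genes left out (0.0052), no filter (0.016) and thinned counts (0.085), and FOXO1 (0.052) without pigs Sample_656, Sample_572 and Sample_735. Of 2430 pairs of a named gene and a left-out pig, 17 differed in call or sign. Of 88 pairs of a gene correlated between tissues and a setting, 25 lost the call. At 2990913 to 6216459 counts per library, thinning to the smallest left 5283 and 4496 genes of 11523 tested.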

Other observations

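Tests chosen after their results were seen were the comparison of fibre levels in adipose, the tests on immune and other lists with library measures or HBB removed or by chromosome, the test on KRT1 and KRT10, the other pairings of tissues, and the search for genes at 2 levels. Regulatory lists were split between the tissues, and camera called none of those that follow. Of 11 immediate early genes, 7 were higher in adipose, such as EGR1 (1.96, SE 0.242), and 2 were higher in muscle: ATF3, a stress-induced transcription factor, at 412 ± 541 CPM in muscle and 21.6 ± 9.57 CPM in adipose (SD, n = 18; -4.25, SE 0.377), and NR4A3, at 122 ± 295 CPM in muscle and 10.9 ± 4.27 CPM in adipose (SD, n = 18; -3.48, SE 0.546; -2.14 with the pig number as a block; list adjusted p = 0.212). Of 12 clock genes 6 were higher in muscle, such as CRY2 (-1.74, SE 0.165), and 2 in adipose (adjusted p = 0.287). Of 14 genes of the growth hormone and IGF axis 5 were higher in adipose, such as IGFBP6 (1.54, SE 0.196), and 6 in muscle, such as GRB10 (-2.06, SE 0.158; adjusted p = 0.606). Heat shock and unfolded protein genes had 3 higher in adipose, with HSPA5 at 0.43 (SE 0.133), and 6 in muscle, with HSPE1 at -1.80 (SE 0.102; adjusted p = 0.262). Of 8 brown-like genes 3 were higher in adipose, such as UCP2 (1.33, SE 0.198), and 4 in muscle, such as UCP3 (-1.84, SE 0.254; adjusted p = 0.611). The 10 glucocorticoid genes had 4 higher in adipose and 5 in muscle, with a median of -0.45 and a mean of -0.01 while camera leaned to adipose (adjusted p = 0.811). Under library totals alone the medians of the clock, growth hormone, heat shock, brown-like and glucocorticoid lists turned to 0.96, 1.23, 0.96, 0.74 and 0.93.

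Some genes lay at 2 separate levels, with the same pigs at the low level in both tissues. SNCG stood at 0.721 to 2.05 CPM in the muscle and 1.02 to 1.52 CPM in the adipose of pigs Sample_176, Sample_572 and Sample_911, and at 24.2 to 96.1 and 28.4 to 119 CPM in the other 15. MMRN2, named here after its values were seen and next to SNCG in the Sscrofa11.1 gene table with 0 protein-coding genes between them, was at 1.12 CPM or less in muscle and 1.45 or less in adipose in 8 pigs, 0 of which were among those low in SNCG, and at 4.93 CPM or more in muscle and 7.54 or more in adipose in the other 10. SMDT1 was at 1.48 CPM or less in muscle and 1.33 or less in adipose in 9 pigs, and at 11 or more and 2.36 or more in the other 9, with 18 of 18 pigs on the same side in both tissues. Its adipose levels lay close together (0.243 to 1.33 and 2.36 to 8.99 CPM), and it did not meet the rule that follows. Over 12542 genes, 7 had a gap of at least 1 in log2 CPM in both tissues with the same pigs on each side, 2 of them with a symbol (SNCG and MMRN2), against 0 genes in each of 99 permuted pairings of the tissues. No explanation was tested.

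Skeletal muscle transcripts varied widely between adipose libraries, with ACTA1 at 335-fold from lowest to highest and a median of 644 CPM. The 32 other sarcomere, fibre and coupling genes of the fixed lists had a median rho of 0.960 with ACTA1 over the 18 adipose libraries, 31 of them at 0.5 or more and BIN1 lowest at 0.352, against a median of 0.0237 for 8401 other named genes, so muscle tissue in some backfat samples is a candidate explanation. Reads passed from the pig's own longissimus library are argued against. In the 4 adipose libraries with the most ACTA1, fibre genes were taken above the level of the adipose libraries with little ACTA1. They did not stand in the proportions of that pig's longissimus. Slow fibre genes exceeded fast fibre genes by 1.004 to 1.949 log2 units more than the same share of it would bring. The rank-sum p was 0.00117 over 6 slow and 7 fast genes, each averaged over the 4 libraries. Fibre genes rise together, so this p does not measure the spread between pigs. Tissue with the proportions of that longissimus sample would meet the same values. Reads passed from longissimus libraries of other pigs cannot be told apart from muscle tissue. The slow minus fast fibre level should then lie within that of longissimus (-3.11 to -0.193). Of these 4 libraries 2 lay outside it, pig Sample_731 at -0.0754 and pig Sample_911 at -0.187, the latter barely. That is too few to exclude this source, and the marginal excess of pig Sample_911 tells little against it. Unlike in the test before, the level of adipose libraries with little ACTA1 was not taken off here. No biological explanation was tested, since the growth class of each pig is in no label used here.

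Scores of 6 lists, most of them immune, varied together in both tissues of a pig, and each list was tested by itself. The 6 are not independent findings, since some pigs recur. Pigs Sample_491, Sample_889 and Sample_991 had the highest adipose scores for cell cycle (1.49, 1.82 and 1.89) and for lymphocyte genes (1.49, 1.18 and 1.37). They did not stand together in every list, as their adipose glucocorticoid scores show (0.195, -0.633 and -1.15). Library total, share of counts outside genes and muscle RNA are argued against as the whole cause for antigen presentation (rho 0.550 with these removed), interferon (0.641), cell cycle (0.552) and glucocorticoid genes (0.556), with a permutation p of at most 0.0191. For macrophage genes these measures fit, since the rho fell from 0.649 to 0.125 (permutation p = 0.621), and for lymphocyte genes they cannot be told apart from a shared state of the pig, since the rho fell from 0.60 to 0.426 (p = 0.0795), too little to decide over 18 pigs. For blood, only what follows the HBB level was tested. That part is argued against as the whole cause for antigen presentation (0.752 with the HBB level removed), interferon (0.775) and macrophage genes (0.581). The same holds for lymphocyte (0.598) and cell cycle genes (0.587), with a permutation p of at most 0.0129 in every case. White blood cells whose amount does not follow HBB were not tested, so blood as a whole stays open. For glucocorticoid genes blood cannot be told apart from a shared state, since the rho fell from 0.742 to 0.470 (p = 0.0512). For antigen presentation, SLA alleles that match the reference unequally cannot be told apart from a shared state, since 7 of the 8 genes lie on the chromosome of the SLA genes and may share their haplotypes. The only other, CIITA (named after its value was seen), had a rho of 0.585 (p = 0.012), and 1 gene is too few to decide. Removing the first principal component ended all 6 list calls. These tests replaced a test over all 6 lists written beforehand, whose median rho was 0.551 with library measures and 0.592 with HBB removed, and then a split into 2 groups of lists, because the lists behaved differently. No biological explanation was tested, since growth class, litter and health of a pig are in no label used here.

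CPHL1, CHIA, PHEROC, GLYATL2 and SCGB1D1 differed widely between adipose libraries, with CPHL1 at 3.72 CPM or less in 3 libraries and 33.7 CPM or more in 15. A secretory epithelium in some backfat samples is a candidate source, on few genes. Of its 31 list genes 6 reached the level tested. Their median rho with CPHL1 was 0.543 (0.555 within the 15 libraries), close to the bound of 0.5. LTF (0.652 to 219 CPM), ST14 (1.74 to 21.6 CPM) and KRT18 (3.15 to 25.5 CPM) passed it, though KRT18 never fell under 2 CPM. KRT8 (rho 0.401), SLC12A2 (0.430) and ANKRD22 (0.146) stayed below it. KRT8 (5.97 CPM) and SLC12A2 (104 CPM) were read in muscle too, and ANKRD22 little (1.05 CPM). The median rho of all other genes with CPHL1 was not computed. For a sebaceous gland the median rho was -0.201 over 5 of 17 genes, but 4 of these stayed at 2 CPM or more in every adipose library, which would hide a small share of gland, so the bound set beforehand was not applied, a decision made after these values were seen, and this source stays open. Epidermis stays open too. KRT1 plus KRT10 had a rho of -0.348 (-0.425 within the 15 libraries), but their sum was at 4.13 to 10.8 CPM in every adipose library, which would hide a small share as well, and the 3 keratinocyte list genes of 18 that reached the level tested had a median rho of 0.771. This test replaced one in a single library, where the sum was 0.369% of CPHL1. KRT15 (rho 0.709), DSP (0.787), TP63 (0.771) and DSG1 (0.681) rose with CPHL1, so other parts of the skin also stay open, and no biological explanation was tested.

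Refits over 100 splits of the 36 libraries, the real one included, tested whether other groupings of the libraries give such counts. For genes higher in adipose (5853) and genes higher in muscle (4919), 1 of 100 splits, the real one, reached the count, and the highest other split gave 4400, so chance can be excluded. That split put the libraries of each of the 18 pigs in different groups, but its first group held 4 adipose libraries, against 18 in the real split. Among splits that keep some pigs whole the highest gave 3996, with 14 adipose libraries in its first group. Both splits parted the tissues unevenly and so carried part of the tissue difference. The median of the other splits was 0 genes in each direction. For the lists, 24 of 100 splits gave 15 or more, with a highest other of 20, so by the bound set beforehand chance was not excluded for that count. The 16 splits with 9 adipose libraries on each side gave at most 9 lists and 0 genes. Every other split that reached 15 parted the tissues unevenly and so carried part of the tissue difference. These splits therefore cannot decide whether chance gives such a count of lists. For the correlation between tissues, 72 genes reached the smallest rho called in the real pairing, against at most 13 in 99 other pairings (1 of 100, the real one). That rho was taken from calls made by permuting the same pig numbers, so a low count in a typical other pairing (median 4) followed from the calls. The comparison is thus no separate evidence against chance. It shows only that none of the 99 other pairings tried came to 72 genes.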
